A study of Mus musculus with 4 samples.

How the data were processed

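PML bodies are nuclear structures organised by the PML protein. ALaP-seq profiles the chromatin close to them: the peroxidase APEX, joined to PML by a knock-in, attaches biotin to nearby chromatin once hydrogen peroxide is given. Per the labels, the samples were E14 mouse embryonic stem cells, a male line, grown with leukemia inhibitory factor, the GSK3 inhibitor CHIR99021 and the MEK inhibitor PD0325901. There were 4 samples in 2 groups, 2 treated with hydrogen peroxide and 2 in which it was omitted as the negative control. Libraries were made with a transposase-based kit and selected for size, per the labels' protocols.

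Per the series' design text, reads were trimmed with Trimmomatic and mapped with bowtie2 version 2.3.5.1 to a repeat-masked mm10 genome, and blacklisted and greylisted regions were then taken out with bedtools. The peak caller, its threshold and the rule by which replicates were merged are not given in the sources used here. The deposited file used here is a peak list of the authors in which, by its name, the replicates are merged; it names no sample, so whether the controls entered it is unknown here. It gives the chromosome, start and end of 26496 peaks that do not overlap, and no height, score or p-value. Width therefore took the place of a score wherever peaks were ranked or a stricter set was needed. The file holds no values per sample, so the depth of each sample is unknown here. The treated samples were not compared with the controls for the same reason, and no spread between replicates was computed. Signal tracks were not analysed here. Intervals and p-values describe this list, with peaks, genes or positions as units, and peaks and neighbouring genes are not independent of each other.

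The list was joined to GRCm38, the assembly that mm10 names, and no peak ran past a chromosome end. Genes came from the GENCODE M21 annotation, with 1 transcription start site (TSS) per gene, the 5' end of its model, which left 21911 protein-coding genes. Peaks were shuffled 1000 times within their chromosome, outside assembly gaps and at their own widths, and 200 of these shuffles served for base composition. The smallest two-sided p these can give is 0.0020 with 1000 shuffles and 0.00995 with 200. A peak was placed by its midpoint at a promoter (within 1 kb of a protein-coding TSS), an exon, an intron or between genes. A gene counted as having a promoter peak when a peak shared at least 1 bp with the window of 1 kb either side of its TSS. Start sites of the same gene outside this window did not count, so a gene without a promoter peak may have one at another start. Peaks per chromosome were tested with exact binomial tests against ungapped length, and windows of 300 kb with exact Poisson tests against their chromosome's mean density. Promoter CpG observed/expected, over 500 bp either side of the TSS, was divided into 10 classes of equal size, numbered from the lowest. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

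A set of 43 gene lists and 18 short sequence words was fixed before the data were examined. Lists were tested at promoters with Fisher's exact test, two-sided, against all other protein-coding genes, with 0.5 added to each cell for the log2 odds. As the alternative, each list was set against 10000 random lists with the same number of genes in each CpG class. For distal peaks, the mean number of peak midpoints within 50 kb of the TSS and outside its own 1 kb window was compared with 10000 random lists matched on the number of protein-coding TSSs in that window. The smallest two-sided p of such a comparison is 0.0002. Lists held protein-coding genes, except those of imprinted genes, small nuclear RNAs and snoRNA hosts, which also held noncoding genes. The words were tested in the sequence from 500 bp upstream to 100 bp downstream of the TSS by logistic regression with GC content, CpG observed/expected and their squares as covariates. Adjusted p-values are Benjamini-Hochberg values over the chromosomes, windows, lists or words of each family, called at 0.05.

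The genes named are those of a rule fixed beforehand: Pml and the list of PML body components, up to 4 members with the widest promoter peak and up to 4 without one for each called list, the 20 genes with the widest promoter peak, the genes of the 10 densest windows, the genes nearest to the 10 widest peaks, and all members of the lists of core pluripotency genes and of the Y short arm. Near-identical copies of the central 150 bp of each peak were sought in GRCm38 with minimap2 2.31, at 95% identity over 80% of the query; highly repeated seeds were skipped.

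The tests were also tried on simulated data. For the promoter list tests, the peak rates per CpG class were set near those observed. Genes of the simulated lists were drawn at random, so families of neighbouring genes were not covered. Of 100 shuffled peak sets set against the others, 5 were called for promoter share, and 0 of 10921 genes given a peak were missed. Both list tests called 4 of 4 planted lists, and of 20 unchanged lists Fisher's test called 1 and the CpG-matched test 0. The distal test called 1 of 1 planted list and 0 of 23 lists without added peaks. Alternatives covered the promoter, distal and window sizes, the overlap needed, the TSS used, the gene set, joined peaks, the wider peaks only (13227), the shuffled background, the chromosome expectation and the comparison lists. Chosen after seeing the data were the list without peaks of the 10 densest windows, the list without peaks that have a near-identical copy, and distal counts without peaks at any protein-coding promoter. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.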

Results

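The 26496 peaks of the merged list covered 7.51 Mb, 0.284% of the ungapped mm10 genome. Their median width was 223 bp, with quartiles of 151 and 354 bp and a range of 91 to 12734 bp. The series holds 2 samples of APEX-PML embryonic stem cells treated with hydrogen peroxide and 2 untreated controls; the list names none of them and carries no value for any single sample. The series set out to profile the genomic regions associated with PML bodies, and the questions addressed here are where the listed peaks lie and which genes they hold. The list was not compared with the controls or with a profile of open chromatin. Whether a given peak reflects closeness to PML bodies was therefore not tested.

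Promoters held far more peaks than their share of the genome, although most peaks lay elsewhere. The midpoints of 8599 peaks (32.5%, 95% interval 31.9 to 33.0%) fell within 1 kb of a protein-coding TSS, 19 times the share of shuffled peaks (1.70% ± 0.0786, SD over 1000 shuffles). Exons held 5.67% of the peaks, 1.59 times the shuffled share. Introns held 25.9% and the sequence between genes 36.0%, 0.70 and 0.63 times their shuffled shares. Each of the 4 categories differed from the shuffles with the smallest two-sided permutation p they can give, 0.0020.

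A promoter peak was found at 8413 of 21911 protein-coding genes (38.4%, 95% interval 37.8 to 39.0%). The share rose with promoter CpG content, from 0.822% of genes in the lowest of 10 classes of CpG observed/expected to 34.3% in class 5, 72.3% in class 9 and 68.9% in class 10. The log2 odds of the highest against the lowest class were 8.02, and the two-sided p of Fisher's exact test was too small to be represented. With only the wider peaks of the list, 24.6% of genes had one at the promoter.

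**Figure D1:**
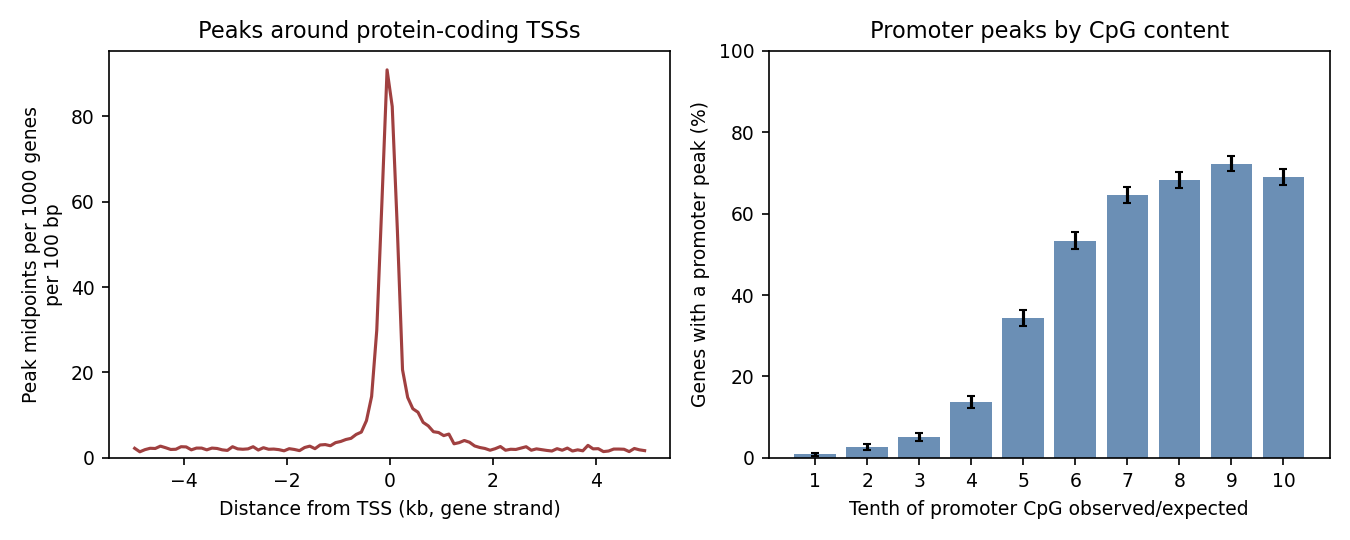
Left, peak midpoints per 1000 protein-coding genes in bins of 100 bp against the distance from the TSS in kb, along the gene's strand. Right, the percentage of protein-coding genes with a promoter peak in each of 10 classes of promoter CpG observed/expected, with exact 95% intervals as bars; it climbs from 0.822% in the lowest to 72.3% in class 9.

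The gene of the tagged protein, Pml, had a promoter peak of 232 bp on chromosome 9 (58249888 to 58250119), upstream of its TSS at 58249786 on the minus strand. Of the 20 genes for PML body components, 15 had a promoter peak. Wide ones lay at Topors (chromosome 4, 40269498 to 40270149, 652 bp), the SUMO protease gene Senp1 (626 bp) and the histone chaperone gene Hira (587 bp). Daxx, whose product is recruited to PML bodies, carried 3 promoter peaks of up to 436 bp, and others with a peak included Sumo2, Sumo3, Rnf4, Trp53, Morc3, Blm, Usp7 and Senp6. Atrx on chromosome X, Crebbp, Hipk2, Pias1 and Sp100 had none. The list exceeded other genes in Fisher's exact test (log2 odds 2.18, adjusted p = 0.00299), but not random lists of equal promoter CpG content, which held 10.9 genes with a peak on average (adjusted p = 0.0826).

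Core pluripotency genes carried promoter peaks at 19 of 24 members, against 9.99 in random lists of equal CpG content (adjusted p = 0.00107; Fisher's exact test, adjusted p = 0.000146). The widest were at Tdgf1, the Nodal co-receptor gene (chromosome 9, 110947036 to 110948363, 1328 bp), and at Sox2 (chromosome 3, 34649667 to 34650554, 888 bp), Rif1 (812 bp) and Nanog (chromosome 6, 122707119 to 122707855, 737 bp). Pou5f1, which encodes Oct4, had 2 promoter peaks, the wider one on chromosome 17 from 35504742 to 35505412. Peaks were also found at Klf2, Klf4, Klf5, Tbx3, Zfp42, Tfcp2l1, Sall4, Zfp281, Gbx2, Dppa5a, Utf1, Lin28a, Dppa2 and Prdm14. The 5 members without one at the TSS used here were Dppa4, Esrrb, Fgf4, Nr0b1 and Nr5a2. Genes reported to lie at embryonic stem cell super-enhancers had a promoter peak at 24 of 30 members (14.2 in matched lists, adjusted permutation p = 0.00107), with the widest at Phc1 (1056 bp) and Spry4 (934 bp). The 2 lists share 16 genes, so their results are not independent.

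Targets of the FGF, LIF and WNT pathways, which the culture medium acts on, had a promoter peak at 23 of 24 members against 14.1 in matched lists (adjusted permutation p = 0.00156). The widest were at Ccnd1 (chromosome 7, 144939568 to 144940607, 1040 bp), Spry4, Pim3 (766 bp) and Axin2, a WNT target (750 bp), and Id1 was the member without one. All 19 heat shock genes had a promoter peak, against 12.5 in matched lists (adjusted permutation p = 0.00156). They included Hspa8 (chromosome 9, 40800729 to 40801709, 981 bp), Hspa9 (806 bp), Hsp90b1 (645 bp) and Hspd1 (618 bp), which encode chaperones of the cytosol, mitochondria and endoplasmic reticulum. Oxidative stress genes had one at 15 of 20 (9.43 in matched lists, adjusted permutation p = 0.0215), among them Txn1 (1082 bp), Prdx1 (872 bp) and Nfe2l2 (687 bp), but not G6pdx on chromosome X, Gclc, Gpx4 or Slc7a11.

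Genes for protein synthesis and respiration formed another group above its matched lists. Promoter peaks were present at 66 of 75 genes of the mitochondrial ribosome (45.4 in matched lists), 71 of 83 cytosolic ribosomal protein genes (52.4) and 64 of 80 genes of oxidative phosphorylation (46.5), each with an adjusted p of 0.00107. Translation factor genes had one at 46 of 58 members (36.9, adjusted permutation p = 0.0288) and splicing factor genes at 42 of 55 (33.5, adjusted p = 0.0288). Examples were Rps19 (958 bp), Rps25 (924 bp), Mrps30 (610 bp), Ndufs1 (792 bp), Eif4a2 (1349 bp) and Hnrnpa1 (1927 bp, a peak shared with the neighbouring Cbx5). Among the ribosomal protein genes without a peak, Rpl10 and Rpl36a lie on chromosome X. Mitotic genes had one at 21 of 24 members (15.6, adjusted permutation p = 0.0426), with Anln (1039 bp) and Birc5 (751 bp) widest and Bub1, Bub1b and Nusap1 without. DNA repair genes had one at 27 of 33 (20.9, adjusted permutation p = 0.0455), including Xrcc4 (833 bp), Msh3 (826 bp), Chek1 (795 bp) and Atm (723 bp). Genes named Zfp with a number, most of which encode zinc finger proteins, had one at 213 of 365 (163, adjusted permutation p = 0.00107).

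Replication-dependent histone genes carried the widest promoter peaks of the list. A promoter peak was present at 57 of 67 members against 44.7 in matched lists (adjusted permutation p = 0.00430), and neighbouring genes shared peaks, so the 57 genes had 37 distinct widest peaks with a median of 1314 bp. Without the peaks of the 10 densest windows, which include a histone window, 39 members had one and the call ended (adjusted permutation p = 0.227). It was kept with only the wider peaks and without peaks that have a near-identical copy (adjusted permutation p = 0.000955 and 0.0344). Of the 20 protein-coding genes with the widest promoter peak, 15 were histone genes. A peak of 3585 bp on chromosome 13 (21715487 to 21719071) covered Hist1h2ai, Hist1h2bl and Hist1h3h, and one of 2799 bp (23760048 to 23762846) lay at Hist1h4a, Hist1h3a and Hist1h1a. Hist1h1d, Hist1h1t, the testis histone gene, Hist1h2aa and Hist1h2ao were among the 10 members without one. The other 5 genes were Tcstv3, a gene of the 2-cell-like state (3192 bp), and the predicted genes Gm10722, Gm11168, Gm10717 and Gm10718 near the start of chromosome 9. The Tcstv3 peak began 941 bp from the TSS and had its midpoint between genes, so little of it lay in the promoter window.

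**Figure D2:**
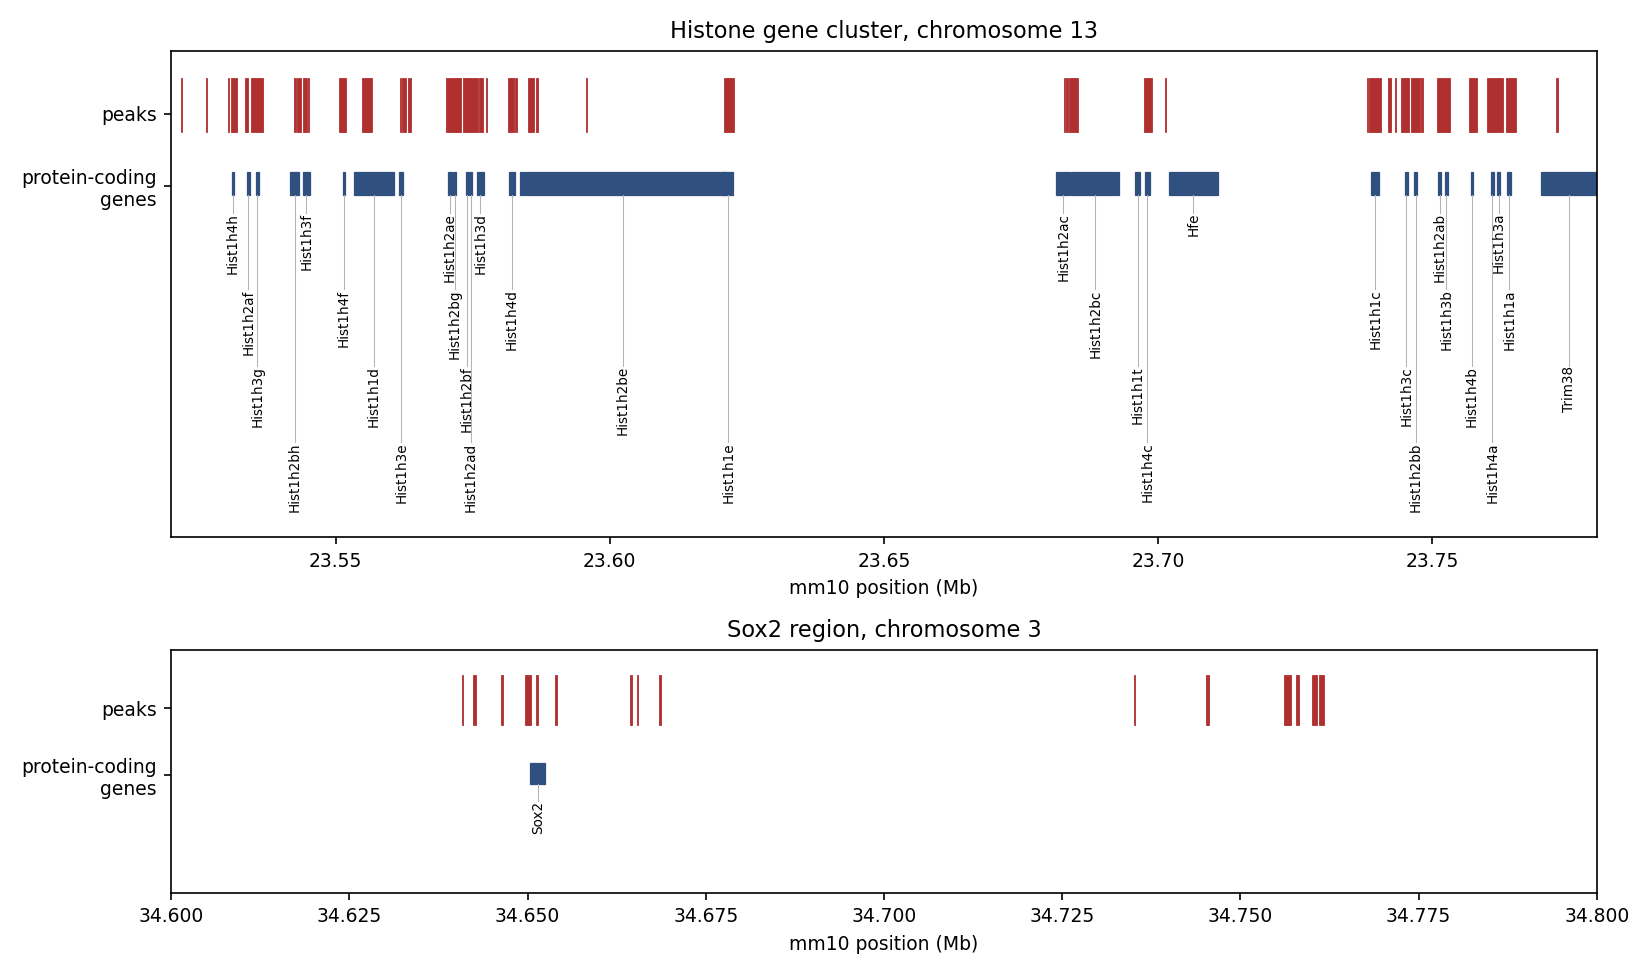
Peaks (red) and protein-coding genes (blue) along mm10 positions in Mb, in a part of the histone gene cluster of chromosome 13 with 46 peaks and in the region of Sox2 on chromosome 3 with 15 peaks. Wide peaks lie over groups of histone genes, whereas the Sox2 region holds peaks at the gene and others away from it.

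Other lists exceeded all other genes in Fisher's exact test but not lists of equal CpG content. These were 11 of the 25 lists above other genes: PML body components, p53 targets (18 of 24), proteasome (25 of 39), S phase (27 of 34), telomere (14 of 16), polycomb (19 of 27), heterochromatin (15 of 21), Mediator and cohesin (26 of 42), small nuclear RNAs (17 of 24), snoRNA hosts (11 of 14) and immediate early genes (17 of 22). With all peaks none passed the matched comparison, in which S phase genes came closest (permutation test, adjusted p = 0.05003). Wide peaks among them lay at Cbx3 (1646 bp, shared with Hnrnpa2b1), Pcna (893 bp), Myc (662 bp), Gas5 (1053 bp) and the U7 small nuclear RNA gene Rnu7 (chromosome 6, 124740251 to 124741774, 1524 bp). With only the wider peaks, the immediate early genes and Mediator and cohesin did not pass Fisher's exact test either (adjusted p = 0.265 and 0.0651). Cdkn1a, the p53 target that encodes p21, had no peak within 1 kb of the TSS used, although it had 13 distal peaks within 50 kb.

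Genes of other tissues and of chemosensation mostly lacked promoter peaks. A peak was present at 2 of 1134 olfactory receptor genes, Olfr823 and Olfr27 (29.9 in matched lists, adjusted permutation p = 0.00107), 1 of 326 vomeronasal receptor genes, Vmn1r4 (7.24, adjusted p = 0.0215) and 1 of 106 keratin genes, Krt23 (11.5, adjusted p = 0.00107). Fisher's exact test also placed liver (0 of 22), blood (0 of 22), muscle (3 of 22, Mylpf, Ckm and Tnnt1), fibroblast (2 of 17, Vim and Fn1), 2-cell-like (3 of 20) and Y short arm genes (1 of 12) below other genes, with adjusted p from 6.76e-05 to 0.0467. At equal CpG content the liver, blood, muscle and fibroblast calls ended (adjusted permutation p from 0.193 to 1), and the 2-cell-like genes lay above their matched lists (log2 ratio 1.56, adjusted p = 0.0740). Without peaks that have a near-identical copy, 1 of 20 2-cell-like genes had a promoter peak, against 0.633 in matched lists. With neighbouring genes counted as 1 locus, the calls of the Y short arm, 2-cell-like, muscle and fibroblast genes also ended in Fisher's exact test (adjusted p = 0.0506, 0.0506, 0.0967 and 0.161), and each ended in 1 or more other settings. Alb and Afp of the liver list and Cd3d of the blood list were among those without a peak, and Tcstv3, Duxf3 and Tdpoz4 were the 2-cell-like genes with one.

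Developmental regulators lay below lists of equal CpG content. A promoter peak was found at 22 of 66 developmental transcription factor genes against 36.3 in matched lists (adjusted permutation p = 0.00156), 13 of 39 Hox genes against 21.2 (adjusted p = 0.0241) and 8 of 31 germline genes against 14.6 (adjusted p = 0.0354). None of these 3 lists differed from all other genes in Fisher's exact test (adjusted p = 0.494, 0.668 and 0.221). Neither test called the genes of DNA methylation (8 of 14), the interferon response (6 of 25), imprinting (14 of 33), neurons (11 of 28), trophoblast (4 of 13) or primitive endoderm (2 of 12). The trophoblast genes with a peak were Tfap2c, Cdx2, Ascl2 and Eomes and those of primitive endoderm Lama1 and Lamb1, named after their values were seen.

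**Figure D3:**
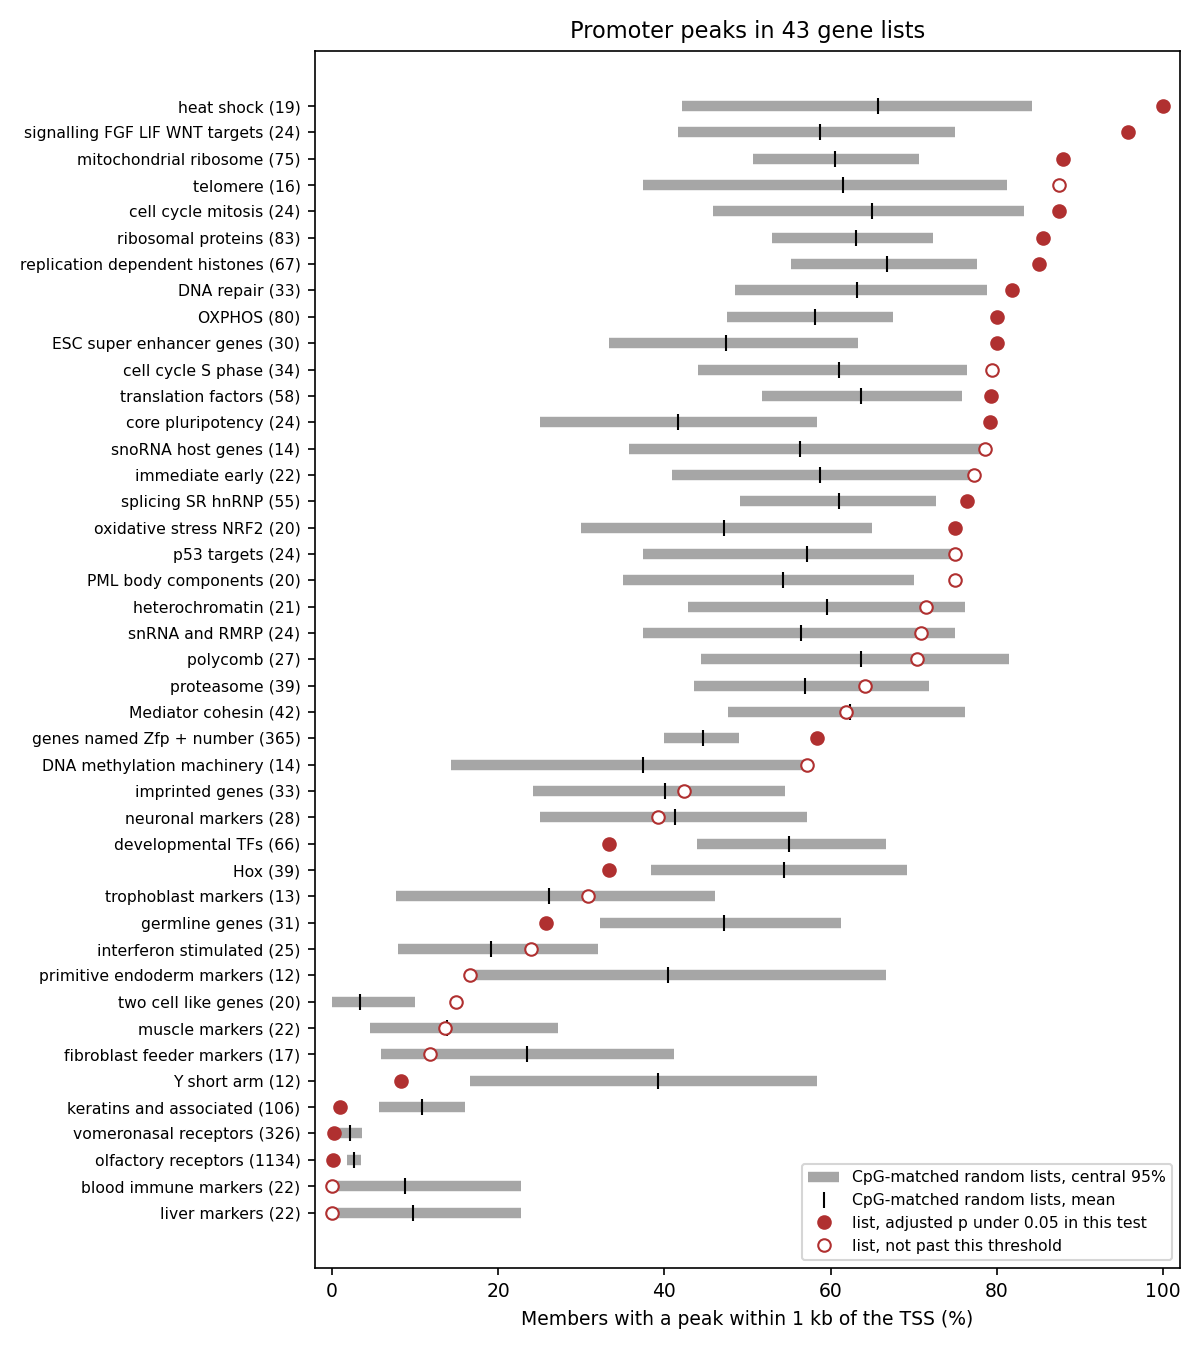
The percentage of members with a promoter peak in each of the 43 gene lists (circles, with the number of members in brackets), beside the mean (tick) and central 95% range (grey) of random lists of equal promoter CpG content. Filled circles passed an adjusted p of 0.05 in this comparison: 14 lists lie above their range and 7 below.

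Around the TSS, outside the promoter, pluripotency genes had several times the peaks of comparable genes. Genes at super-enhancers had 7.67 distal peaks per gene within 50 kb against 1.51 in random lists matched on TSS density, core pluripotency genes 6.17 against 1.57, and targets of FGF, LIF and WNT 5.67 against 1.42 (adjusted permutation p = 0.000955, 0.00156 and 0.000955). Fgf4, without a peak at the TSS used, had 14 distal peaks, Tbx3 had 13, Nanog 12 and Pou5f1 11. Esrrb and Nr0b1, the latter on chromosome X, had 1 each. Pml had 14, but the list of PML body components was not called in this comparison. With 1 TSS per gene, a peak at another start site of the gene can count as distal. Histone genes had 15.1 against 4.32, small nuclear RNA genes 6.25 against 1.78, heat shock genes 5.89 against 2.33 and Hox genes 7.95 against 4.22 (adjusted p from 0.000955 to 0.00156). In clustered families the same peak counts for several neighbouring genes.

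Further distal excesses were called for the genes of DNA methylation (4.86 against 2.07), heterochromatin (4.95 against 2.40), polycomb (4.59 against 2.07), snoRNA hosts (4.57 against 1.85), immediate early genes (4.55 against 2.32), ribosomal proteins (3.99 against 2.75), Zfp genes (3.35 against 2.15) and developmental transcription factors (2.33 against 1.37), which made 15 lists. The 5 lists below their random lists were olfactory receptors (0.347 against 3.36), vomeronasal receptors (0.359 against 1.70), keratins (0.321 against 3.55), Y short arm genes (0 against 1.25) and liver genes (0.955 against 2.15). Without peaks at the promoter of any protein-coding gene, a comparison chosen after seeing the data, the snoRNA hosts no longer passed (adjusted permutation p = 0.0565), and super-enhancer genes had 6.93 against 1.14. The call of the developmental factors ended with unmatched lists (adjusted permutation p = 0.627), as did that of the liver genes (adjusted p = 0.0679). Within 20 kb the calls of the Y short arm and liver genes ended (permutation test, adjusted p = 0.0733 and 0.0738), and within 100 kb those of the developmental factors and liver genes (adjusted p = 0.111 and 0.164).

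Chromosome X was almost empty of peaks. It held 185 peaks where its ungapped length gives 1636, a ratio of 0.113 (95% interval 0.0974 to 0.131), and 40 of its 948 protein-coding genes (4.22%) had a promoter peak, against 31.3 to 47.1% on the autosomes. Chromosome Y held 43 peaks, 0.0488 of its expectation, and 34 of them lay near its end between 90717615 and 90829846. On the short arm of Y, Eif2s3y, which encodes a translation initiation factor subunit, had a promoter peak of 546 bp (1010251 to 1010796), and Ddx3y, H2al2b, H2al2c, Kdm5d, Rbmy, Sry, Uba1y, Usp9y, Uty, Zfy1 and Zfy2 had none. Of chromosome Y, 96.3% is repeat-masked, and against unmasked bases its ratio was 0.84 (exact binomial test, adjusted p = 0.277). That ratio rests on the 34 peaks near the end, 24 of which have a near-identical copy elsewhere; only 9 peaks lay on the rest of the chromosome.

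Among the autosomes, chromosomes 11, 17, 9, 13, 4 and 19 held the most peaks for their length, with ratios of 1.68, 1.57, 1.41, 1.38, 1.37 and 1.35. Chromosomes 3 (0.762), 14 (0.775) and 12 (0.834) held the fewest. In exact binomial tests 9 chromosomes were above and 9 below expectation, X and Y included. Per protein-coding TSS the order was different but the spread was not smaller: the ratio was highest on chromosome 13 (1.60) and lowest among autosomes on 7 (0.695), and chromosomes 4 (1.30), 9 (1.17) and 17 (1.13) stayed above expectation. The calls of chromosomes 11 (1.01, exact binomial test, adjusted p = 0.754), 3 (0.984, adjusted p = 0.673) and 6 (1.00, adjusted p = 1) ended, while chromosomes 1, 7, 12, 16, 18 and 19 changed direction. Chromosome 2, at 1.01 by length and not called, also fell below expectation per TSS.

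**Figure D4:**
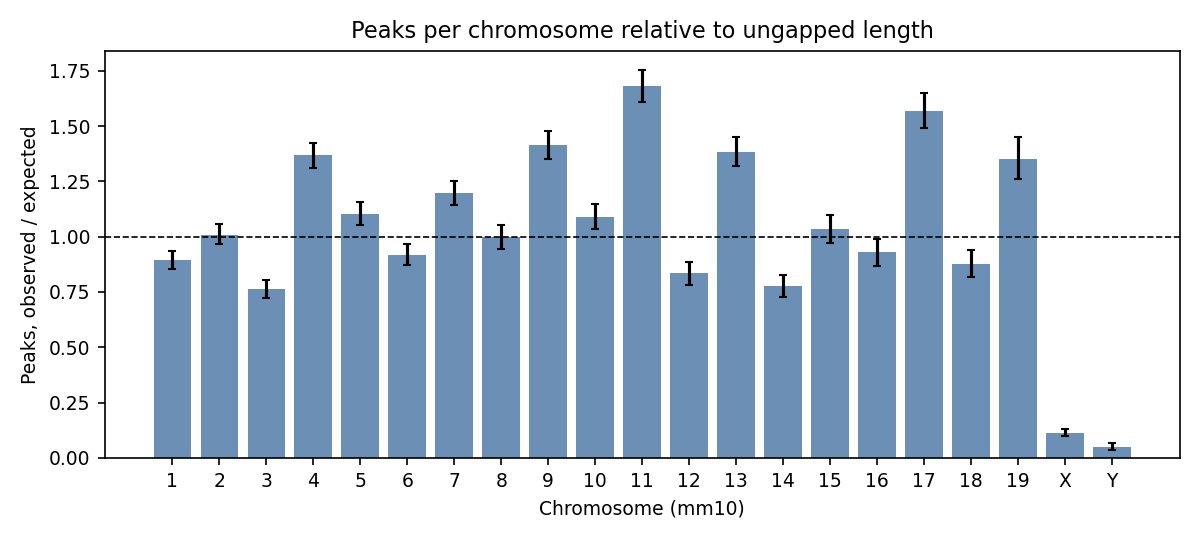
Peaks per chromosome divided by the number expected from ungapped length, with exact 95% intervals as bars and a dashed line at 1. Chromosome 11 is highest at 1.68, and X (0.113) and Y (0.0488) are lowest.

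Peaks were clustered along the genome. The densest window of 300 kb, on chromosome 4 from 147300001, held 85 peaks where 4.10 were expected and the zinc finger genes Zfp982, Zfp978, Zfp985 and Zfp988 with Gm16503. It was followed by windows on chromosome 1 from 85200001 (74 peaks, C130026I21Rik), chromosome 13 from 23400001 (65 peaks, histone genes), chromosome 9 from 124200001 (65 peaks, 2010315B03Rik, Ppp2r3d and Gm21836) and chromosome 13 from 12600001 (59 peaks, Prl2c3, of the prolactin family). The other 5 lay on chromosome 11 from 3000001 (53 peaks, Sfi1, Eif4enif1, Drg1 and Patz1), chromosome 17 from 30600001 (52 peaks, Glo1 and Dnah8), chromosome 12 from 86700001 (45 peaks, Irf2bpl, Cipc, Lrrc74a, Angel1 and Zdhhc22) and chromosome 4 from 147000001 (44 peaks, Zfp991 and Rex2) and 146400001 (42 peaks, Zfp981, Zfp992 and Zfp993). Of 9096 windows, 774 passed an exact Poisson test after adjustment, and 3800 held no peak. Ranked by covered bases instead, 4 of these 10 windows stayed among the first 10. Of the 584 peaks in these 10 windows, 217 (37.2%) have a near-identical copy elsewhere in the genome, from 0% in the windows of Glo1 and Irf2bpl to 77.0% in that on chromosome 1.

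The widest peak, of 12734 bp, lay between genes on chromosome 9 (123924523 to 123937256), 31435 bp from the TSS of the chemokine receptor gene Ccr1. The next were on chromosome Y in an intron of Gm47283 (5958 bp), on chromosome 9 near Ppp2r3d (3924 bp) and again on Y (3662 bp), followed by the histone, Tcstv3 and Gm11168 peaks above, one in an intron near Sfi1 (2450 bp) and one 4331 bp from the TSS of Sirt4 (2405 bp). The median distance to the nearest peak was 6.19 kb, against 30.6 ± 0.308 kb (SD) in shuffled lists (permutation p = 0.0020, the smallest possible). Joining peaks within 5 kb left 18684 regions, 4625 of them with at least 2 peaks and one with 65. Against positions shuffled only within 10 kb of protein-coding TSSs, the distance was longer, not shorter, by a ratio of 1.30 (permutation p = 0.00995, the smallest possible).

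Peaks were rich in GC and CpG. Mean GC content was 56.8% against 42.1% in shuffled positions, and CpG observed/expected was 0.457 against 0.179 (each permutation p = 0.00995, the smallest possible). Against positions shuffled within 1 kb of protein-coding TSSs the contrasts were smaller, with 50.6% GC and a CpG observed/expected of 0.402. Peaks outside promoters had 52.9% GC against 42.0%. The repeat-masked share was 16.3%, against 33.5% in shuffled positions and 16.8% in those near TSSs; mapping to a repeat-masked genome lowers this share by itself, so it was not read as a property of the regions. Although mapping was to a repeat-masked genome per the design text, 347 peaks (1.31%) lay wholly in bases that the reference used here masks.

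At equal GC and CpG content, 8 of 18 promoter words went with a peak. The word of THAP11 had the highest log2 odds (1.59 ± 0.39 SE, logistic regression, n = 21911 promoters, adjusted p = 0.000151), although only 91 promoters held it. It was followed by the words of ETS factors (0.78 ± 0.07, n = 21911, adjusted p = 2.12e-28), YY1 (0.72 ± 0.15), NRF1 (0.57 ± 0.15), ZFP143 (0.56 ± 0.10), the GC box (0.30 ± 0.06), the CCAAT box (0.23 ± 0.05) and E2F (0.20 ± 0.08, adjusted p = 0.0318). The THAP11 word contains the ZFP143 word on the opposite strand, so these are not separate sequences. The TATA box had log2 odds of -0.20 (n = 21911, adjusted p = 0.0755), and the words of SOX, octamer, ESRRB, p53 and AP1 factors did not pass either. Without the covariates the CCAAT box changed direction (-0.05, Fisher's exact test, adjusted p = 0.201), and in the shorter promoter sequence NRF1 no longer passed (adjusted p = 0.0551).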

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

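The alternatives without the peaks of the densest windows, without peaks that have a near-identical copy and without peaks at any protein-coding promoter were chosen after seeing the data, and the others before. No paired analysis was possible because the samples share replicate numbers but the only list is merged, names no sample and has no values per sample, which also rules out leaving out a replicate. The depth per sample is unknown, so what it limits cannot be stated. Of the values for single chromosomes, categories, lists and words, 664 stayed on their side of the threshold. A further 27 newly passed it, 50 no longer did, 9 changed direction and 1 otherwise moved. Of the main results, 47 were kept, 8 moved and 1 changed direction. Direction was compared only where the main value had passed the threshold, so changes of direction among the others are not counted. Peaks stayed above shuffled shares at promoters, and X below its expectation, under every alternative run for them.

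Counted per TSS, chromosomes 1, 12, 16 and 18 moved above expectation (1.18, 1.26, 1.10 and 1.24) and 7 and 19 below (0.695 and 0.907). Chromosome 2, not called by length, also fell below. Nearest peaks lay farther apart than positions shuffled near TSSs, by a ratio of 1.30. The share of genes with a promoter peak was 36.1% within 500 bp, 41.1% within 2.5 kb, 37.7% with 100 bp of overlap, 42.4% over every transcript start and 24.6% with the wider peaks. Matching on CpG content lowered the lists above other genes from 25 to 14. Of the called lists, it turned the 2-cell-like genes (log2 ratio 1.56) and Mediator and cohesin (-0.0092). The ratio of the 2-cell-like genes was 0.405 without peaks that have a near-identical copy. Counting neighbouring genes as 1 locus left 5 of 9 lists below other genes, without the Y short arm, 2-cell-like, muscle and fibroblast genes, and a distal window of 20 kb left 3 of 5, without the Y short arm and liver genes. Without covariates the CCAAT box had log2 odds of -0.053. The cause of these differences was not tested.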

Other observations

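The tests on chromosome X, on near-identical copies in the dense windows and on copies at histone genes were chosen only after the result was seen, and the bounds for the X peak widths and the histone copies were set with the values known; those on extra copies in the cell line and on neighbouring start sites were not.

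Protein-coding genes that share a divergent promoter, with another TSS on the opposite strand within 1 kb, had a promoter peak at 1142 of 1483 (77.0%), against 35.6% of other genes (Fisher's exact test, two-sided p = 3.06e-216) and 884 genes given by their CpG classes. Their window holds another TSS by definition, so a peak at either can count for both genes, which raises the share by itself. The test also took paired genes as independent, and the CpG classes correct for neither. Noncoding genes less often had a promoter peak: 19.5% of antisense genes, 9.76% of lincRNA genes, 8.60% of miRNA genes, 6.01% of snoRNA genes and 4.19% of snRNA genes. Midpoints within 1 kb of a TSS lay upstream in 50.8% of cases, and the bin just upstream of the TSS was the fullest, with 90.9 per 1000 genes. Of the 34 peaks near the end of chromosome Y, 24 have a near-identical copy elsewhere, as do 6.12% of all peaks and 10.3% of shuffled positions.

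Chromosome X held few peaks. Base composition and masking are argued against, since X promoters with a peak were 0.136 times the mean of autosomal lists of equal CpG content (39 of 945 against 287, 95% range 266 to 310; 3 X genes, 1 with a peak, had no CpG value and were left out) and peaks per unmasked Mb were 0.129 times the autosomal value. X promoter peaks were narrower, with a median of 153 bp against 282 bp on autosomes, a ratio of 0.543 (bootstrap 95% interval 0.482 to 0.660), which is what a lower signal from the single X of a male line could give. A weaker contact of X with PML bodies predicts the same, and with 1 cell line and no peak heights the 2 cannot be told apart. No biological explanation was tested.

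Over the 10 densest windows 37.2% of peaks have a near-identical copy (bootstrap 95% interval over windows 19 to 55.1%), against 6.12% of all peaks, so reads shared between copies are a candidate explanation that stays open, as the interval reaches below the 20% it needs. The share was 44.7 to 77.0% in the windows on chromosomes 1 and 4 and that of Prl2c3, and 9.23, 13.2 and 16.9% in the histone window and those of Sfi1 and Ppp2r3d. Extra copies in the cell line could spread peaks evenly, and were weighed for the windows of Glo1 and Irf2bpl, singled out because none of their 97 peaks has a near-identical copy: the share of peaks at promoters was 1.32 times the share of promoter bases (95% interval 0.275 to 3.76), which rests on 3 peaks, all in the Irf2bpl window (3 of 45 against 0 of 52 in the other). The interval runs past the ratio of 3 this explanation allows, so it stays open, and no biological one was tested.

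Histone promoter peaks were wide, with a median of 1314 bp (bootstrap 95% interval 1010 to 1731) against 276 bp at other genes. Start sites close together are argued against as the whole cause, because the 90th percentile of 954 peaks at other genes with a TSS within 1 kb was 607 bp. Near-identical copies of the peak centre are too, with 6 of 37 peaks having one (16.2%, 95% interval 6.19 to 32.0%), below the 50% the explanation was held to need. The bound against it was first a share under 20%, which the interval does not meet, and was changed once the value was known. Copies of the centre are therefore argued against only as the source of most of these peaks. Because only the central 150 bp was searched, at 95% identity, copies of other parts of these wide peaks, or less similar ones, would be missed and stay open. Joining of neighbouring peaks when the list was made was not tested and stays open, and no biological explanation was tested.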
